A study of Mus musculus with 22 samples.

How the data were processed

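Total RNA of 22 mouse bladders was read on Agilent arrays in 1 colour (Cy3), 1 array per sample. There were 8 groups: normal (3 arrays), Krt5-Cre (2), Upk2-Cre (2), Trp53 het (3), Krt5-Cre R270H (3), Krt5-Cre R172H (4), Upk2-Cre R270H (2) and Upk2-Cre R172H (3), the last 7 with BBN. Per the file headers, the spot intensities were made with Agilent Feature Extraction 11.0.1.1, which subtracted background and removed spatial trends within an array. Version 9.1 is named per the submitters' processing notes, and the headers were followed. The deposited normalized table holds log2 values that the authors had brought to a common distribution between arrays. This scaling was read from the values themselves, since every column has the same highest value (18.8), and the steps are not given in the sources used here. Each of its columns ranked its probes exactly as its own array does (Spearman correlation 1), and dim or flagged spots are empty in it. The limma package is named per the submitters' processing notes, without a version.

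The processed spot signal of each array was taken as log2 and the 75th percentile of the unflagged non-control spots of that array was subtracted. Spots flagged as outliers (53 to 301 per array) were left out, and the remaining spots of a probe were averaged. Of 56605 non-control probes, 32994 carried 1 gene symbol, 0 several and 23611 none; the last were left out of the gene tests because they have no name in the sources used here. Gene names followed GRCm38.p6, and no genome was used. The brightest probe stood for each of the 22911 genes with a symbol. A gene was tested if its probe was well above background on at least 2 of the 22 arrays, which left 17426 genes, of which 6263 had 2 or more tested probes. A flagged value removed 15 genes.

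The fit was limma 3.58.1 in R 4.3.3, with 8 group means over all 22 arrays and 9 contrasts. Groups within a side of a contrast were weighted alike, so that the mean of a side is the mean of its group means, while its SD is taken over its arrays. Genes with a Benjamini-Hochberg adjusted p at or under 0.05 within a contrast were called changed. The 22 gene lists (356 genes, 342 of them tested) were written from general knowledge of bladder and tumour biology. They were tested against all other genes with camera in limma at its preset correlation of 0.01 between genes, and beside that with the correlation estimated from the data, under which 0 lists were called in every contrast. Members were also adjusted over the list alone. A list's score on an array is the mean deviation of its genes from their average over the arrays. For the basal, squamous, luminal and p53 target lists the scores were compared in 8 contrasts with exact two-sided permutation tests, 32 in all and adjusted together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the rest.

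Genes are named by rule. Trp53, Krt5, Krt14, Upk2 and Cdkn1a are always given. To these come the 10 highest and 10 lowest called genes of a contrast (predicted genes and clone names skipped), up to 4 members of smallest p of each list described, and the 5 genes of smallest p where none passed. Genes picked out after their values were seen are said to be so.

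The fit was tested on simulated data with 200 genes changed out of 17426. With a planted log2 change of 2 it recovered 69.0% of them for BBN against normal, 46.5% for Krt5 mutant against Krt5-Cre, 51.5% for Upk2 mutant against Upk2-Cre, 23.5% for the driver difference, 71.0% for Krt5 against Upk2 mutant, 84.0% for Krt5 mutant against the other BBN groups, 70.5% for Krt5 mutant against Trp53 het, 55.0% for Trp53 het against the Cre controls and 71.5% for R270H against R172H. With a planted change of 1 it recovered between 0% and 46.0%, and with 4 between 70.5% and 98.5%. An absent call therefore leaves 2-fold changes open in every contrast.

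Groups, contrasts, lists and most alternatives were set before the data were examined. The alternatives were normexp background correction (offset 50, on median spot and background brightness, as the files hold no mean brightness), quantile normalization, the deposited table, no filter, a strict filter (all arrays; 11128 genes), the mean over probes, only the arrays compared, blocks for slide, scanner and replicate number, a sex label covariate, arrays sharing an animal code averaged, array weights and each array left out in turn. Further alternatives were chosen after seeing the data: a covariate of Xist minus the Y-linked genes, 2 arrays in doubt by sex left out, dim arrays left out, only the scanner of the normal arrays, the first part of the animal code as a block, the fry test for lists and scores of all 22 lists. Slide cannot be fitted as a fixed block for BBN against normal, since slide 4 holds all normal arrays and no other, so it was a random block there.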

Results

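The data are RNA levels in 22 mouse bladder samples, each read on 1 one-colour Agilent array. Mice of 7 groups, with 19 arrays, drank N-butyl-N-(4-hydroxybutyl)nitrosamine (BBN), a carcinogen that acts on the bladder, for 24 weeks and were sampled at 8 months of age. The groups with an activated mutation carried 1 mutant Trp53 allele together with a tamoxifen-inducible Cre recombinase, driven in basal cells by the Krt5 promoter or in luminal cells by the Upk2 promoter. The mutant alleles were R270H, a change at the DNA contact surface of p53, and R172H, a change that unfolds its DNA-binding domain. There were 3 Krt5-Cre R270H, 4 Krt5-Cre R172H, 2 Upk2-Cre R270H and 3 Upk2-Cre R172H bladders. The BBN groups without an activated mutation were Krt5-Cre (2 bladders), Upk2-Cre (2 bladders) and Trp53 het (3 bladders, with neither Cre nor tamoxifen). Trp53 het titles give 1 lost allele, while the genotype entry names the R270H allele. Without Cre that allele was not recombined, so both labels can name the same mice. A further 3 normal bladders came from wild-type mice that received neither tamoxifen nor BBN. Their tissue label names urothelium, while the extraction protocol names whole bladders for every sample.

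Between 42.4% and 63.2% of the 59305 non-control spots of an array were well above background, and 0 spots were saturated. Slides 1 and 2 were read by 1 scanner model (42.4% to 57.2% of spots above background) and slides 3 and 4 by another (56.3% to 63.2%). Slide 4 held the 3 normal bladders and nothing else, so that normal tissue and slide 4 cannot be told apart. Levels are log2 signals relative to the 75th percentile of their array, so that 0 is the level of that percentile. Xist, the RNA that silences an X chromosome in females, and 4 Y-linked genes went against the sex label on 11 of the 22 arrays. These were all 3 normals, all 4 Krt5-Cre R172H arrays, 2 Upk2-Cre R172H arrays, Upk2-Cre replicate 2 and Trp53 het replicate 3. None of these 11 had both Xist and a Y-linked gene well above background. Arrays with Xist and at least 2 Y-linked genes above it were not counted. Of the other 11, Krt5-Cre replicate 2 had Xist and 1 of the 4 Y-linked genes above it.

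**Figure D1:**
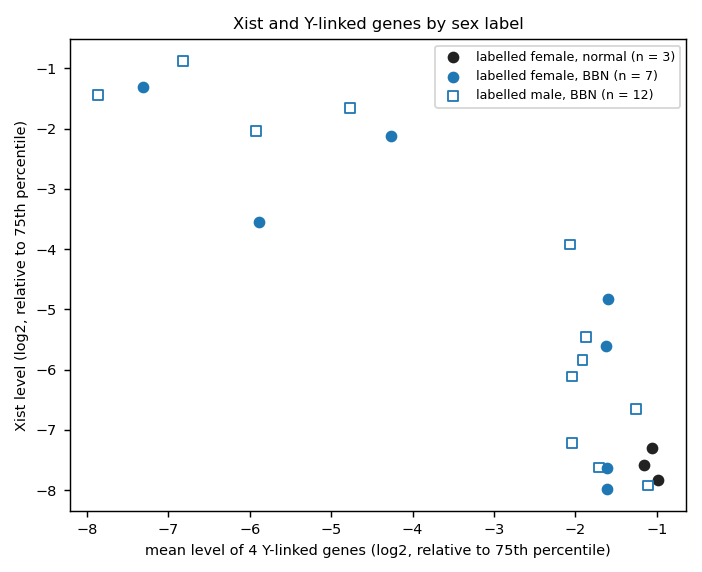
Level of Xist (vertical axis) against the mean level of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty (horizontal axis), both as log2 relative to the 75th percentile of the array, 1 point per array and coloured by sex label and treatment. The 3 normal arrays are labelled female and lie with the Y-positive arrays, and 7 of the 19 BBN arrays are Xist-positive.

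Trp53, the mutated gene itself, was measured first. Its level was −1.12 ± 0.10 (SD, n = 3) in normal bladders, 0.36 ± 0.63 (n = 2) in Krt5-Cre, 1.14 ± 0.63 (n = 2) in Upk2-Cre and 0.68 ± 1.03 (n = 3) in Trp53 het bladders. Among the mutants it was −0.79 ± 0.58 (n = 3) in Krt5-Cre R270H, −0.33 ± 1.08 (n = 4) in Krt5-Cre R172H, −0.99 ± 0.42 (n = 2) in Upk2-Cre R270H and −0.23 ± 1.30 (n = 3) in Upk2-Cre R172H. The probe reads both alleles together, and whether the mutant allele was recombined was not tested. The Trp53 het mean lay between the Cre controls, and all mutant means below. Trp53 passed the test in none of the 9 comparisons that follow.

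The 7 BBN groups were compared with the normal bladders to ask what 24 weeks of carcinogen did. The normals also differed in slide and genotype, and only they and Trp53 het had no tamoxifen. The tissue label of the normals names urothelium. Differences are therefore not assigned to BBN alone. Basal and squamous genes rose and luminal genes fell. Krt6a, a keratin of stressed and squamous epithelium, rose on the log2 scale from −4.74 ± 0.61 (SD, n = 3) to 8.26 ± 1.05 (SD, n = 19; limma adjusted p = 1.09e-09). Krt14, a keratin of basal cells, rose by 7.97 to 8.85 ± 0.80 (n = 19) from 0.88 ± 1.04 (n = 3; limma adjusted p = 2.26e-08), and its basal partner Krt5 by 1.87 (adjusted p = 0.000689). In the list of basal urothelial and keratinocyte genes, 16 of 20 measured members rose and 0 fell, 16 and 0 also when adjusted over the list alone, with further examples in Krt17 at 11.62 and the desmosomal cadherin Dsg3, at least 77.7-fold higher. The list was called higher by limma camera (median log2 change 2.22, adjusted p = 1.36e-08; adjusted p = 0.255 with an estimated correlation). Squamous differentiation genes, which build the cornified envelope of keratinizing epithelium, rose in 20 of 27 cases and fell in 1 (21 and 1 adjusted over the list alone). Examples were Calml3 at 9.11, the plakophilin Pkp1 at 4.28, Cnfn, at least 1568-fold higher, and Sprr3, at least 222-fold higher; the exception, picked out after its value was seen, was Ivl (involucrin) at −2.15. The squamous list had a median of 4.19 (camera adjusted p = 1.25e-06; adjusted p = 0.514 with an estimated correlation). Genes of luminal and urothelial differentiation fell in 15 of 25 cases and rose in 3 (16 and 3 adjusted over the list alone; median −1.80, camera adjusted p = 3.97e-05; adjusted p = 0.137 with an estimated correlation).

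The uroplakins, membrane proteins of the urothelial surface, led that loss. Upk3a fell by 9.02 from 7.61 ± 0.26 (SD, n = 3) to −1.41 ± 2.50 (n = 19; limma adjusted p = 0.000142), Upk2 fell by 5.81 (adjusted p = 8.71e-06), Upk1a fell by 5.27, and Snx31, a partner of uroplakins, was at least 34.5-fold lower. The members that rose were Gpx2 at 3.11, Elf3 at 0.85 and Klf5 at 0.75, picked out after their values were seen. A score per array, the mean deviation of a list's genes, was compared as well. The basal score was 0.58 ± 0.61 (SD, n = 19) in BBN and −3.70 ± 0.12 (n = 3) in normal bladders, the squamous score 0.61 ± 1.54 against −3.85 ± 0.15, and the luminal score −0.32 ± 0.47 against 2.03 ± 0.13. In each of the 3 lists, 19 of 19 BBN arrays lay beyond all 3 normals (exact two-sided permutation p = 0.000649, the smallest that 1540 splits allow; Benjamini-Hochberg adjusted p = 0.00693 over 32 score tests).

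**Figure D2:**
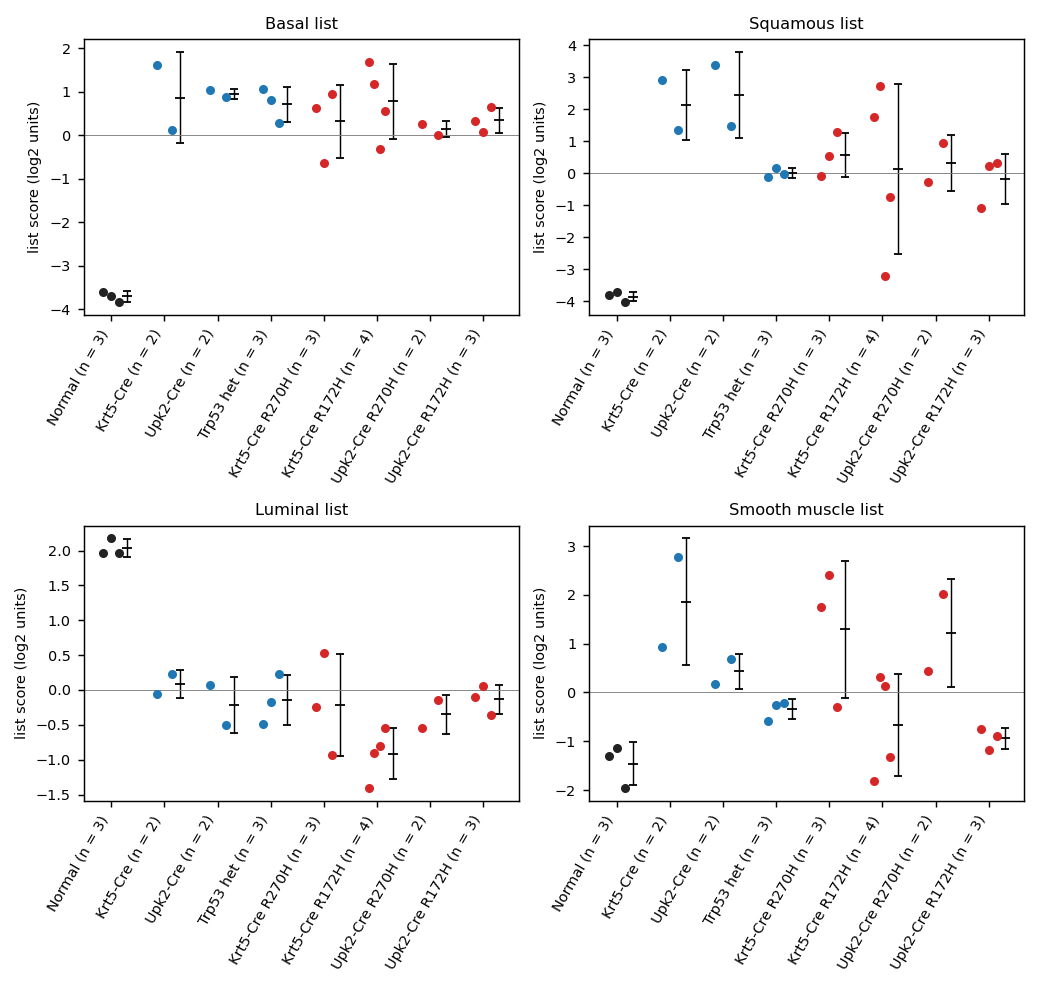
Scores of the basal, squamous, luminal and smooth muscle lists by group, as mean log2 deviation of the list's genes from their average over all 22 arrays. Each point is an array, the bar beside it is the group mean ± SD, black marks normal bladders, blue BBN bladders without an activated mutation and red those with one; the basal score of normal bladders is −3.70 ± 0.12 (n = 3), below all 19 BBN arrays.

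Inflammation and proliferation genes rose as well. Ltf (lactoferrin, a neutrophil granule protein) was at least 3736-fold higher in BBN bladders, Cxcl5, a neutrophil attractant, at least 313-fold higher, and S100a9 rose by 8.39. Of 20 genes of neutrophils and acute inflammation, 15 rose and 0 fell, as also adjusted over the list alone (median 4.21, camera adjusted p = 6.58e-07; adjusted p = 0.253 with an estimated correlation). Among cell cycle genes 31 of 32 rose and 0 fell (32 and 0 adjusted over the list alone), among them Ube2c at 5.17 and the mitotic kinase Plk1 at 4.60 (median 3.60, camera adjusted p = 1.12e-18; adjusted p = 0.255 with an estimated correlation). Interferon response genes rose in 9 of 13 cases with 0 lower, counted either way, with the antiviral genes Oas1a at 4.24 and Isg15 at 3.92 (median 2.43, camera adjusted p = 0.00168). Lymphocyte genes rose in 6 of 17 cases and fell in 0, counted either way, with Cd3e of the T cell receptor at 2.23 (0.94 with scanner as a block, limma adjusted p = 0.104) and Foxp3 of regulatory T cells at least 3.84-fold higher (median 1.33, camera adjusted p = 0.0294). Glycolysis and hypoxia genes rose in 9 of 15 cases and fell in 0, counted either way, with Pfkp at 2.46 and Pgk1 at 2.32 (median 1.54, camera adjusted p = 0.00206). With an estimated correlation the interferon and lymphocyte lists had adjusted p = 0.538 and the glycolysis list adjusted p = 0.514.

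Genes of the bladder wall moved apart. Smooth muscle genes rose in 11 of 14 cases and fell in 0, counted either way, with the contractile proteins Cnn1 at 3.75 and Des at 3.76 (median 1.76, camera adjusted p = 0.00214). Fibroblast genes fell in 8 of 12 cases and rose in 0, counted either way, with Pi16 at −3.40 and Pdgfra at −2.80 (median −2.41, camera adjusted p = 0.000312). Hedgehog and BMP pathway genes, which carry signals between epithelium and stroma, fell in 8 of 11 cases and rose in 1, counted either way, with Bmp5 at −5.45, Gli1 at −5.28 and Hhip at −7.49; the exception was Smo at 0.61, picked out after its value was seen (median −3.92, camera adjusted p = 8.28e-05). NRF2 target and xenobiotic genes fell in 7 of 15 cases and rose in 1, counted either way, with Cyp1a1 at −6.20 and Gstm1 at −4.82, both of which act on foreign compounds; the exception was the cystine carrier Slc7a11 at 1.84 (median −0.79, camera adjusted p = 0.0270). These 4 lists had adjusted p = 0.538 with an estimated correlation (smooth muscle and NRF2), 0.514 (fibroblast) or 0.137 (hedgehog).

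The p53 target list moved both ways in BBN bladders. Of its 25 measured genes 6 rose and 4 fell (6 and 5 adjusted over the list alone), with Gdf15 at 2.87, Phlda3 at 1.46 and Ei24 at −1.09. Its median was 0.03 and −0.15 after quantile scaling (camera adjusted p = 0.967), and its score differed by 0.21 (exact two-sided permutation p = 0.148; n = 19 and 3). Cdkn1a, the cell cycle inhibitor p21 that p53 induces, rose by 1.43 (limma adjusted p = 0.0165) but by 0.41 on its other probe, and lost its call without normal replicate 1 (1.30, adjusted p = 0.0832), without normal replicate 3 (1.33, adjusted p = 0.0794) with the scanner as a block (0.78, adjusted p = 0.170), with the mean over probes (0.92, adjusted p = 0.134) and with the sex label as a covariate (1.38, adjusted p = 0.0543). Trp53 was −0.02 ± 1.03 (SD, n = 19) against −1.12 ± 0.10 (n = 3; limma adjusted p = 0.0950). Matrix remodelling genes split into 6 higher and 5 lower of 20 (6 and 6 adjusted over the list alone), with the proteases Mmp3, at least 8.51-fold higher, and Mmp13, at least 14.6-fold higher, against lower collagens such as Col3a1 at −2.10; the list's median was −0.45 and its mean 0.38. The macrophage list had 5 higher and 1 lower of 13 (5 and 1 adjusted over the list alone; median 0.69) and the list of epithelial-mesenchymal transition 3 higher and 1 lower of 12 (2 and 1; median −0.08). Other lists not called by camera had few or no members past the test over all genes or over the list alone. Antigen presentation had 0 of 13 (0, median 0.42) and endothelium 1 lower of 10 (0, median −0.55). Schwann cells and nerve had 1 higher of 7 (1, median −0.43, mean 0.14) and adipocytes 1 lower of 8 (1, median 1.38). Skeletal muscle had 2 higher of 9 (2, median 1.53). Male accessory genes, above background on at most 2 arrays, get no value.

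In all, 7435 of 17426 tested genes (42.7%) changed between BBN and normal bladders, 4119 higher and 3316 lower (limma adjusted p under the threshold). Which direction held the majority depended on the setting: quantile scaling gave 3237 higher and 3745 lower, the deposited normalized values 2834 and 3077, and scanner as a block 2557 and 2640. Of the 7435, 3297 were at least doubled and 2337 at least halved. The median of all genes lay at 0.13, and at −0.01 after quantile scaling, a shift of −0.15, against which these changes are to be set. The highest called genes beyond those above were Krt6b (a keratin, at least 3673-fold), Sprr2d (a cornified envelope protein, at least 808-fold), Lgals7 (a keratinocyte galectin, at least 998-fold), Stfa1 (a protease inhibitor, at least 1644-fold), Msln (mesothelin, at least 871-fold) and Calm4 (an epidermal calmodulin-like protein, at least 545-fold). The lowest were Cyp4f15 at −9.41, Wfdc15b at −8.46, Fam183b at least 50.6-fold lower, the integrin Itga11 at −7.67, the transporter Slc47a1 at −7.40, Uchl1 (a ubiquitin hydrolase of neurons) at −7.12 and Pkhd1 at −6.75. An "at least" fold is given for genes well above background on no array of the dimmer group. It sets the brighter group's mean against the dimmer group's mean of, per array, the lowest signal among probes well above background or the gene's own signal where that was higher. The limma camera call of lymphocyte genes was lost without Upk2-Cre R270H replicate 2 (adjusted p = 0.0566), with no filter (0.0547), with slide as a random block (0.0509) and with scanner as a block (0.0620). The hedgehog and NRF2 calls were lost with the deposited normalized table (adjusted p = 0.203 and 0.0595) and with the strict filter (0.196 and 0.0660). The NRF2 call was also lost with Xist minus the Y-linked genes as a covariate, chosen after seeing the data (adjusted p = 0.0521). No block by slide can be fitted here, and with slide as a random block 5178 genes were called.

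**Figure D3:**
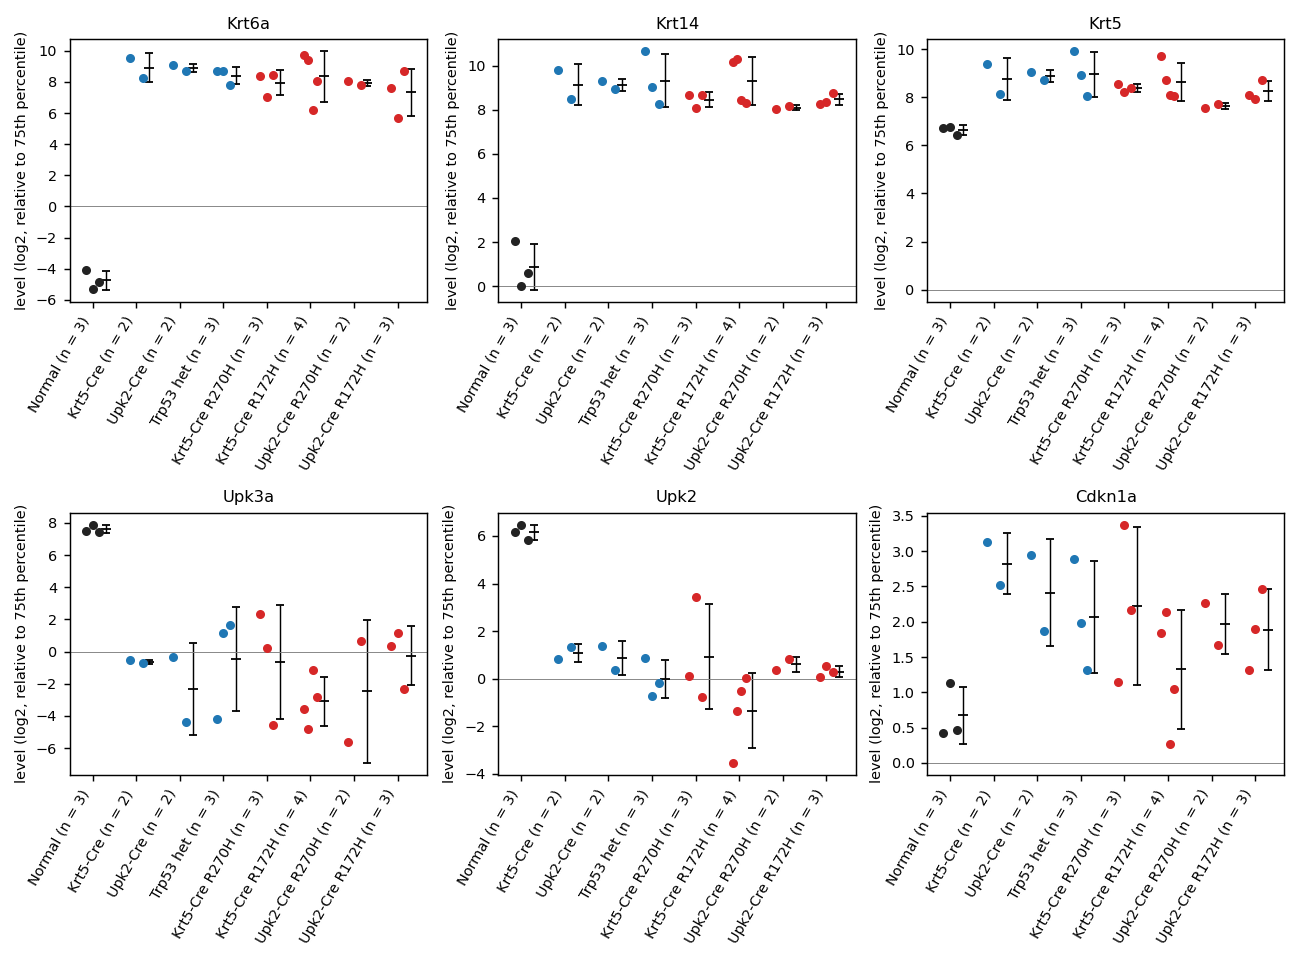
Levels of Krt6a, Krt14, Krt5, Upk3a, Upk2 and Cdkn1a by group, as log2 relative to the 75th percentile of the array. Each point is an array and the bar beside it the group mean ± SD; Upk3a is 7.61 ± 0.26 (n = 3) in normal bladders and −1.41 ± 2.50 (n = 19) over the BBN bladders.

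What a Trp53 mutation in Krt5-expressing basal cells adds to BBN was asked in 7 Krt5 mutant and 2 Krt5-Cre bladders. Xaf1, an interferon-induced gene that promotes apoptosis, was higher by 6.57 in the mutants, at 2.40 ± 1.44 (SD, n = 7) against −4.18 ± 0.24 (n = 2; limma adjusted p = 0.0162), but its other probe read −0.78. Rwdd3, which aids protein modification by SUMO, fell by 1.98 (limma adjusted p = 0.0409), and no other gene of 17426 passed, with 836 at an unadjusted p under 0.05. Krt5 differed by −0.26, Krt14 by −0.26, Upk2 by −1.29, Cdkn1a by −1.05 and Trp53 by −0.92, and none of them passed. As a group, squamous genes were lower in the mutants (median −1.98, 1 of 27 above 0, camera adjusted p = 5.08e-08), with the suprabasal keratin Krt10 at −2.46 and Ivl at −1.51. The squamous score differed by −1.81 (exact two-sided permutation p = 0.278). NRF2 target and xenobiotic genes were lower too (median −0.93, camera adjusted p = 2.52e-07), with Cyp1a1 at −3.77, Cyp1b1 at −2.50 and the quinone reductase Nqo1 at −2.51. No gene of either list passed over all genes, while 0 squamous and 3 NRF2 genes passed adjusted over the list alone. The 2 lists had adjusted p = 0.378 and 0.264 with an estimated correlation. The squamous median was −1.28 without Krt5-Cre R172H replicate 3, whose squamous score was −3.20, and −0.92 without Krt5-Cre replicate 2.

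Among the other lists called between Krt5 mutant and Krt5-Cre bladders, smooth muscle (median −1.64) and luminal genes (−0.33) were lower and cell cycle (0.50) and matrix remodelling genes (0.96) higher. Examples were the muscle myosin Myh11 at −2.08, the uroplakin Upk1a at −2.64, the mitotic kinase Cdk1 at 1.07 and the matrix protein Tnc at 2.48, none of which passed. Camera also called macrophage (0.46), endothelial (0.78) and glycolysis genes (0.36) higher, and nerve (−0.83) and hedgehog genes (−0.51) lower. It called male accessory gland genes lower too, but their 4 tested members were well above background on at most 2 of the 9 arrays, so they are given no value. Over these 10 lists 0 genes passed over all genes, 1 each of nerve and male accessory gland genes passed adjusted over the list alone, and the adjusted p lay between 0.264 and 0.577 with an estimated correlation. Without Krt5-Cre replicate 1 the smooth muscle (−0.67), luminal (−0.74), cell cycle (0.14), glycolysis (−0.09), nerve (−0.02), male accessory and hedgehog (−0.38) calls were lost, and without replicate 2 the matrix (0.25), macrophage (−0.27) and endothelial (−0.02) calls. The macrophage call was also lost without Krt5-Cre R270H replicate 2 (0.27), Krt5-Cre R172H replicate 2 (0.30) or Krt5-Cre R172H replicate 3 (0.40). The endothelial call was lost without Krt5-Cre R270H replicate 2 (0.50), and the hedgehog call without Krt5-Cre R270H replicate 1 (−0.54) or 3 (−0.43). Xaf1 and Rwdd3 both lost their limma calls without Krt5-Cre replicate 1 (adjusted p = 0.132 for each), without Krt5-Cre replicate 2 (0.135 and 0.577) and without Krt5-Cre R270H replicate 2 (0.0682 and 0.0777). Rwdd3 also lost it without Krt5-Cre R270H replicate 1 or 3 or Krt5-Cre R172H replicate 1, 3 or 4 (adjusted p from 0.0704 to 0.0943). Calls also ended under other settings: nerve and hedgehog genes with the deposited normalized values, the strict filter and slide as a block, luminal genes with slide as a block, and hedgehog genes with scanner or replicate number as a block. Normexp and array weights each ended the macrophage call (0.24 and 0.27), and array weights the endothelial call (0.56). Without the dim arrays, a setting chosen after seeing the data, the matrix (0.50) and endothelial (0.10) calls were lost and the macrophage median was −0.28. Xaf1 lost its limma call under 8 other settings (adjusted p from 0.0565 to 0.954) and Rwdd3 under 10 (from 0.0572 to 0.866).

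**Figure D4:**
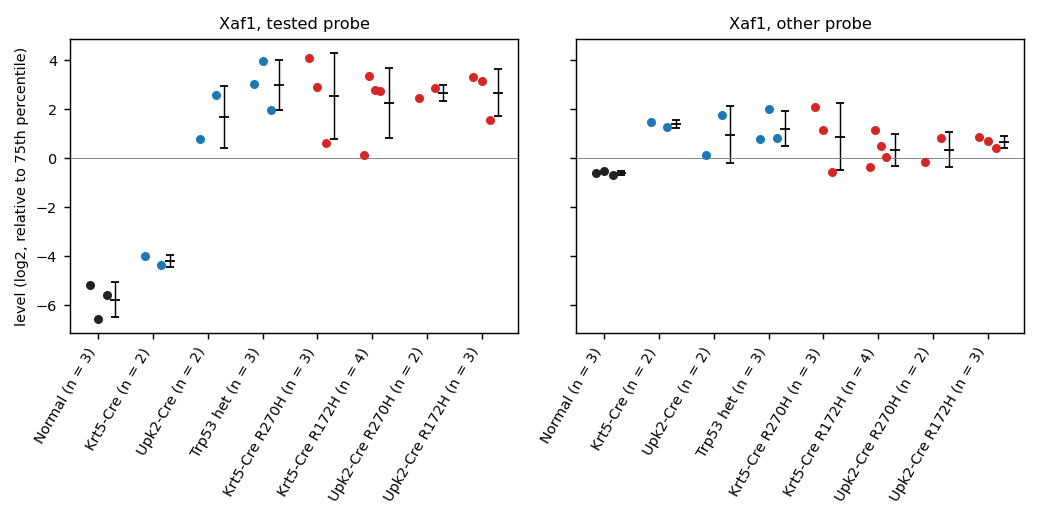
Levels of the tested and the other probe of Xaf1 by group, as log2 relative to the 75th percentile of the array, 1 point per array. The tested probe lies at or above 0.15 on 17 arrays and at or below −4.00 on the 5 Krt5-Cre and normal arrays, while the other probe reads between −0.69 and 2.08.

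Whether the same mutations act alike from luminal cells was asked in 5 Upk2 mutant and 2 Upk2-Cre bladders. Squamous genes were again the lowest group (median −2.54, 1 of 27 above 0, camera adjusted p = 9.43e-10; adjusted p = 0.453 with an estimated correlation), with loricrin (Lor), the main protein of the cornified envelope, at −4.47 and Lce3f at −6.18. The squamous score was 0.03 ± 0.76 (SD, n = 5) in mutants and 2.44 ± 1.35 (n = 2) in Upk2-Cre bladders (exact two-sided permutation p = 0.0476, the smallest that 21 splits allow; adjusted p = 0.218). Trp53 het scored 0.01, so this drop is not assigned to the mutation either. Basal genes were lower (median −0.61, camera adjusted p = 0.00511), with Krt17 at −1.72 and Krt5 at −0.94, as were cell cycle genes (median −0.38, camera adjusted p = 0.0267), with Birc5 at −0.79. Endothelial genes had a median of 1.95 (camera adjusted p = 1.21e-10), with the receptor Tek at least 3.33-fold higher and Cdh5 at 2.44. Genes of epithelial-mesenchymal transition had a median of 1.51 (camera adjusted p = 1.91e-07), with the filament protein Vim at 2.87 and Snai1 at 2.33. Matrix remodelling genes (1.19, with the collagen Col3a1 at 2.12), fibroblast genes (1.38, with Mfap5 at 2.74) and macrophage genes (0.49, with the scavenger receptor Cd163 at least 3.38-fold higher) were called as well. Of all these list members 0 passed over all genes, and adjusted over the list alone 6 endothelial genes and Vim passed; the lists had adjusted p between 0.174 and 0.895 with an estimated correlation.

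Only Hddc3, a pyrophosphohydrolase, passed over all 17426 genes between Upk2 mutant and Upk2-Cre bladders. It rose from −4.85 ± 0.09 (SD, n = 2) to −1.85 ± 0.34 (n = 5; limma adjusted p = 0.0369), and 1093 genes had an unadjusted p under 0.05. The lowest signal well above background on Upk2-Cre replicate 2 was −3.43, which is above the Hddc3 level of that group. Krt14 differed by −0.83, Upk2 by −0.42, Cdkn1a by −0.48 (1.05 on its other probe) and Trp53 by −1.75, and none passed. The limma call of Hddc3 was lost without any 1 of the 7 arrays: Upk2-Cre replicate 1 (adjusted p = 0.353) or 2 (0.219), Upk2-Cre R270H replicate 1 (0.0872) or 2 (0.0751), and Upk2-Cre R172H replicate 1 (0.115), 2 (0.0904) or 3 (0.0701). Without Upk2-Cre replicate 1 the basal (−0.89) and cell cycle (−0.16) calls were lost, without Upk2-Cre replicate 2 the macrophage call (0.15), which also took the squamous median to −1.06. The cell cycle call was lost too without Upk2-Cre R270H replicate 2 (−0.29) or Upk2-Cre R172H replicate 2 (−0.24). Hddc3 lost its limma call under 11 other settings too (adjusted p from 0.0712 to 0.898), with 1.01 under normexp. The basal, cell cycle and macrophage calls were lost with the deposited normalized values, with the strict filter and with the sex label as a covariate. The cell cycle call was also lost with normexp (−0.30), with slide (−0.39) or scanner (−0.38) as a block and with the Xist covariate (−0.17).

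Whether the mutant effect depends on the driver was asked by subtracting the Upk2 effect from the Krt5 effect. Cell cycle genes were relatively higher with the Krt5 driver (median 0.91, 32 of 32 above 0, camera adjusted p = 1.22e-07), with Plk1 at 1.58 and Top2a, which untangles replicated DNA, at 1.36. Between the mutants themselves the cell cycle median was 0.03 (−0.02 after quantile scaling; not called), and the mean cell cycle scores of the controls were −0.04 in Krt5-Cre and 0.86 in Upk2-Cre (n = 2 each). NRF2 target and xenobiotic genes were relatively lower (median −1.04, camera adjusted p = 5.91e-06), with Akr1b8 at −2.21 and Nqo1 at −2.44, both of which detoxify reactive compounds. Also relatively lower were fibroblast (−1.46, with Pi16 at −2.58), smooth muscle (−1.32, with Lmod1 at −2.10), endothelial (−1.19, with Esam at −1.21), nerve (−1.18, with Gap43 at −3.20) and epithelial-mesenchymal transition genes (11 of 12 below 0, with Zeb1 at −2.43). Glycolysis and hypoxia genes (0.88, with the carbonic anhydrase Car9 at 3.24) and adipocyte genes (1.98, with Retn at 2.39) were higher. Lower were p53 target (−0.34, with Zmat3 at −1.62), luminal (−0.32, with Pparg at −1.94) and hedgehog genes (−1.13, with Shh at −4.02; median 0.07 under normexp). Male accessory gland genes were called lower too, but their 4 tested members were well above background on at most 2 of the 16 arrays, so they are given no value. No gene passed, either over all 17426 genes in limma (577 at an unadjusted p under 0.05, smallest adjusted p = 0.661) or adjusted over the list alone (0 in each of the 13 lists). The smallest p-values belonged to Gxylt2, Hddc3, Fam124a, Cbx2 and Ifnk, of which Gxylt2 and Ifnk were well above background on neither Upk2-Cre array and are given no value. The others that did not pass were Hddc3 at −2.95, Fam124a at −4.10, Cbx2 at 1.73, Trp53 at 0.83, Krt5 at 0.68, Krt14 at 0.58, Upk2 at −0.86 and Cdkn1a at −0.57. With an estimated correlation the lists had adjusted p = 0.356 or 0.369.

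The driver difference leaned on single control arrays. Without Krt5-Cre replicate 1 only 2 of the 13 lists stayed called (3 lists in all), and the lost ones had medians of −0.34 for smooth muscle, 0.20 for fibroblast, −0.45 for endothelial, −0.54 for epithelial-mesenchymal transition, −0.39 for nerve and for p53 target, 0.45 for glycolysis, 1.20 for adipocyte, −0.38 for hedgehog and −0.28 for luminal genes; the male accessory call was lost as well. Without Upk2-Cre replicate 1 the endothelial (−0.63), glycolysis (0.53), hedgehog (−0.37), luminal (−0.19) and male accessory calls were lost, and without Upk2-Cre replicate 2 the adipocyte (1.16) and p53 target (−0.37) calls. Without Krt5-Cre R270H replicate 1 the adipocyte (1.55), hedgehog (−1.05), luminal (−0.22) and male accessory calls were lost, without replicate 2 the adipocyte call (1.93), and without replicate 3 the hedgehog (−0.87), luminal (−0.19) and male accessory calls. The luminal call was also lost without Krt5-Cre R172H replicate 1 (−0.26) or 2 (−0.36) or Upk2-Cre R270H replicate 2 (−0.41), which ended the hedgehog call too (−0.93). The male accessory call was also lost without Krt5-Cre replicate 2, Krt5-Cre R172H replicate 3 or 4, Upk2-Cre R270H replicate 1 or Upk2-Cre R172H replicate 3, and the p53 target call without Upk2-Cre R270H replicate 1 (−0.19). The cell cycle and NRF2 calls were kept without any 1 array. Under normexp the hedgehog median turned to 0.07 and the male accessory call was lost. The hedgehog, nerve, luminal and adipocyte calls were lost with the deposited normalized values and with the strict filter (adipocyte medians 0.04 and 0.10), and the epithelial-mesenchymal transition call with the former (−0.92). Quantile scaling (−0.99), the sex label as a covariate (−0.85) and replicate number as a block (−1.11) each ended the hedgehog call. The luminal call was lost with the mean over probes (−0.32) and scanner as a block (−0.29), the adipocyte call with slide as a block (1.37) and array weights (1.30), and the p53 target call with the sex label (−0.34).

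To ask whether a mutation made in basal or luminal cells leaves a different bladder, 7 Krt5 mutant were compared with 5 Upk2 mutant bladders. Hddc3 was lower by 2.29 on the log2 scale in Krt5 mutants, at −4.15 ± 0.44 (SD, n = 7) against −1.85 ± 0.34 (n = 5; limma adjusted p = 0.0132), and no other gene passed (925 at an unadjusted p under 0.05). It was not well above background on 5 of the 7 Krt5 mutant arrays, and its call was lost with slide (limma adjusted p = 0.0625) or replicate number (0.0565) as a block. Both Upk2-Cre R270H arrays were on slide 2 and all 3 Upk2-Cre R172H arrays on slide 3. Adipocyte genes were higher (median 2.36, camera adjusted p = 5.13e-05), but 4 of the 8 were well above background on no Upk2 mutant array, and the median was 1.11 with these at their bound. On the 2 members left by the deposited normalized values and the strict filter it was −0.13 and −0.10. Among the 4 were Cfd (adipsin), at least 14.4-fold higher, and Cidec, a lipid droplet protein, at least 4.13-fold higher. Endothelial genes were lower (9 of 10 below 0, camera adjusted p = 5.13e-05), with Cdh5 at −1.14. Lymphocyte (0.86, with the B cell marker Ms4a1 at least 1.49-fold higher) and skeletal muscle genes (1.38, with the myosin Myh4 at least 2.11-fold higher) were higher. NRF2 target (−0.51, with Slc7a11 at −2.06), p53 target (−0.20, with Zmat3 at −1.07), luminal (−0.22, with Pparg, a driver of urothelial differentiation, at −1.34) and epithelial-mesenchymal transition genes (−0.23, with Vim at −1.16) were lower. Of these list members 0 passed over all genes, and 4 adipocyte genes and Ms4a1 passed adjusted over the list alone. Trp53 differed by 0.05, Krt5 by 0.56, Krt14 by 0.60, Upk2 by −0.65 and Cdkn1a by −0.15, none past the test. With an estimated correlation the lists had adjusted p = 0.423 or 0.455.

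Several of these calls between the drivers ended without 1 array. Without Krt5-Cre R270H replicate 1 the NRF2 (−0.25), luminal (−0.31), p53 target (−0.12) and epithelial-mesenchymal transition (−0.02) calls were lost, without replicate 2 the lymphocyte call (0.59), and without replicate 3 the luminal (−0.11) and epithelial-mesenchymal transition (−0.16) calls. Without Upk2-Cre R270H replicate 1 the lymphocyte (0.39), p53 target (−0.09) and epithelial-mesenchymal transition (−0.19) calls were lost and Hddc3 had limma adjusted p = 0.148, and without replicate 2 the luminal call (−0.19) was lost and Hddc3 had adjusted p = 0.0699. Hddc3 had limma adjusted p = 0.0700 without Upk2-Cre R172H replicate 1. The p53 target call was also lost without Upk2-Cre R172H replicate 3 (−0.05), and the epithelial-mesenchymal transition call without Upk2-Cre R172H replicate 2 (−0.03) or Krt5-Cre R172H replicate 2 (−0.18). With the deposited normalized values 2 lists were called and with the strict filter 3, against 8: both ended the luminal, lymphocyte, adipocyte and epithelial-mesenchymal transition calls, and the former the p53 target call. The epithelial-mesenchymal transition call was also lost with normexp, quantile scaling, the mean over probes, the sex label and slide, scanner or replicate number as a block (medians from −0.35 to −0.10). Array weights ended the p53 target (−0.12), lymphocyte (0.54) and skeletal muscle (0.52) calls. Hddc3 had limma adjusted p = 0.521 with normexp (−0.72), 0.405 with quantile scaling and 0.0739 with only the arrays compared, and had no value for this comparison with the deposited normalized values or the strict filter.

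To ask what sets Krt5 mutants apart, 7 were compared with the 12 bladders of the other BBN groups. Krt5 itself was at 8.51 ± 0.57 (SD, n = 7) and 8.51 ± 0.72 (n = 12), and Krt14 differed by 0.05. Matrix remodelling genes were higher (median 0.51, camera adjusted p = 4.43e-06; adjusted p = 0.336 with an estimated correlation), with the collagenase Mmp13 at 1.77, Mmp3 at 1.48 and Tgfbi, a matrix adhesion protein, at 0.91. Luminal genes were lower (median −0.26, camera adjusted p = 0.000224; adjusted p = 0.336 with an estimated correlation), with Pparg at −1.07 and the uroplakin Upk1b at −1.32. The luminal score was −0.61 ± 0.62 (SD, n = 7) against −0.15 ± 0.27 (n = 12; exact two-sided permutation p = 0.0350, adjusted p = 0.218). Squamous (median −0.70, with Ivl at −1.07), NRF2 target (−0.38, with Slc7a11 at −1.27) and p53 target genes (−0.20, with Aen at −0.42 and Apaf1, which goes against the list, at 0.45) were lower. Higher were lymphocyte (0.40, with Cd5 at 0.86), adipocyte (1.57, with Retn at 2.28) and skeletal muscle genes (0.75, with Actn3 at 1.47). No gene passed in limma over all 17426 genes (875 at an unadjusted p under 0.05, smallest adjusted p = 0.513), and adjusted over the list alone 3 matrix and 2 adipocyte genes passed. Values that did not pass were Rwdd3 at −1.02, Mttp at −1.07, Col10a1 at 2.59, Rgs16 at 1.21, Defb48 (well above background on 2 of 7 and 0 of 12 arrays), Trp53 at −0.75, Upk2 at −0.77 and Cdkn1a at −0.46. The other 6 lists had adjusted p between 0.369 and 0.849 with an estimated correlation.

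The matrix and luminal calls against the other BBN groups held without any 1 array. The squamous call was lost without Krt5-Cre R172H replicate 3 (median 0.07, camera adjusted p = 0.610) or Krt5-Cre R270H replicate 1 (−0.57), the latter also ending the NRF2 (−0.18) and p53 target (−0.10) calls. The skeletal muscle call was lost without Krt5-Cre R172H replicate 3 (0.29), the p53 target call without Upk2-Cre R270H replicate 1 (−0.16) or Upk2-Cre replicate 1 (−0.14), and the lymphocyte call without Krt5-Cre R270H replicate 2 (0.29), Krt5-Cre R172H replicate 2 (0.20) or Upk2-Cre R270H replicate 1 (0.29). Without Krt5-Cre replicate 1, 12 lists were called, and 13 with slide or scanner as a block. The lymphocyte and adipocyte calls were lost with the deposited normalized values (0.29 and 0.03), the strict filter (0.31 and 0.03) and array weights (0.07 and 0.72). Array weights also ended the squamous (−0.27), p53 target (−0.08) and skeletal muscle (0.29) calls, and replicate number as a block the squamous call (−0.39).

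An activated mutation was set against the Trp53 het state in 7 Krt5 mutant and 3 Trp53 het bladders. These differ also in Cre and tamoxifen. Whether the unrecombined R270H allele of Trp53 het acts as 1 lost copy of the gene was not tested. Muscle and vessel genes were higher in Krt5 mutants: skeletal muscle (median 1.52, camera adjusted p = 4.25e-05, with the actin Acta1 at 1.52), smooth muscle (0.61, 14 of 14 above 0, with Cald1 at 0.80) and endothelial genes (0.81, with Kdr, a receptor for VEGF, at 1.06). Matrix remodelling (0.32, with Mmp3 at 2.45), lymphocyte (0.53, with Cd5 at 1.28), fibroblast (0.34, with Cd34 at 1.12), epithelial-mesenchymal transition (0.35, with Twist1 at 1.26) and adipocyte genes (0.87, with Retn at 1.76) were higher too. So were NRF2 target and xenobiotic genes (0.22, with the xenobiotic gene Cyp1b1 at 1.57). Luminal (−0.43, with Krt19 at −0.95) and p53 target genes (−0.25, with the exonuclease Aen at −0.62) were lower. No gene passed in limma over all genes (662 at an unadjusted p under 0.05, smallest adjusted p = 0.999), and adjusted over the list alone only Mmp3 passed. Trp53 was −0.56 ± 0.87 (SD, n = 7) against 0.68 ± 1.03 (n = 3), a difference of −1.24, and Krt5 differed by −0.45, Krt14 by −0.44, Upk2 by −0.18 and Cdkn1a by −0.29. The smallest p-values belonged to Mttp at −1.46, the DNA repair gene Mgmt at −2.09, Eml3 at −1.05, Soat2 at −1.63 and Rab6b at 3.08, none of which passed. With an estimated correlation the lists had adjusted p between 0.489 and 0.690.

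Only the skeletal muscle call held without any 1 array in this comparison. Without Trp53 het replicate 2 the matrix (−0.18), endothelial (0.41), epithelial-mesenchymal transition (0.05), fibroblast (−0.00), p53 target (−0.10) and NRF2 (0.04) calls were lost, leaving 5 lists, and without Krt5-Cre R270H replicate 2 the smooth muscle (0.27), endothelial (0.44), lymphocyte (0.43), epithelial-mesenchymal transition (0.25), fibroblast (−0.06), adipocyte (0.89), p53 target (−0.24) and NRF2 (0.23) calls. Without Trp53 het replicate 1 the luminal (−0.34), adipocyte (0.78) and p53 target (−0.23) calls were lost, and without replicate 3 the lymphocyte (0.30), fibroblast (0.36), adipocyte (0.93) and NRF2 (0.23) calls. The p53 target and adipocyte calls were also lost without Krt5-Cre R270H replicate 1 (−0.15 and 0.54) or Krt5-Cre R172H replicate 3 (−0.16 and 0.74), which ended the fibroblast (0.22) and epithelial-mesenchymal transition (0.28) calls too. Without Krt5-Cre R172H replicate 1 the p53 target (−0.21) and NRF2 (0.25) calls were lost, without replicate 2 the p53 target call (−0.17), and without Krt5-Cre R270H replicate 3 the luminal (−0.35) and NRF2 (0.07) calls. With array weights 5 lists were called against 11: the p53 target median turned to 0.01, and the smooth muscle (0.01), fibroblast (0.04), endothelial (0.46), epithelial-mesenchymal transition (0.21), adipocyte (0.74) and NRF2 (0.32) calls were lost. The deposited normalized values and the strict filter each ended the epithelial-mesenchymal transition, lymphocyte, fibroblast and adipocyte calls. The p53 target call was lost with the strict filter, the sex label, averaged animal codes and scanner as a block, the luminal call with slide as a block (−0.14), and the NRF2 call with slide (0.10) or scanner (0.21) as a block.

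Trp53 het and Cre control bladders both lack an activated mutation. To ask what Cre and tamoxifen, or the unrecombined allele, bring, 3 of the former were compared with 4 of the latter. Squamous genes were lower in Trp53 het bladders (median −2.40, camera adjusted p = 1.76e-14; adjusted p = 0.353 with an estimated correlation), with Lor at −4.02 and Hrnr, another cornified envelope gene, at −4.14. The squamous score was 0.01 ± 0.15 (SD, n = 3) against 2.29 ± 1.02 (n = 4; exact two-sided permutation p = 0.0286, the smallest that 35 splits allow; adjusted p = 0.218). Smooth muscle genes were lower (median −1.45, 0 of 14 above 0, camera adjusted p = 3.45e-11; adjusted p = 0.353 with an estimated correlation), with Synpo2 at −2.62. So were NRF2 target and xenobiotic genes (median −0.84, camera adjusted p = 4.03e-08; adjusted p = 0.267 with an estimated correlation), with the xenobiotic gene Cyp1b1 at −3.65 and Nqo1 at −2.49. Matrix remodelling (0.64, with Timp1 at 1.80) and macrophage genes (0.77, with the complement gene C1qc at 0.90) were higher and skeletal muscle genes lower (−1.37, with Acta1 at −1.42; adjusted p = 0.646 with an estimated correlation for each). No gene passed in limma over all genes (841 at an unadjusted p under 0.05, smallest adjusted p = 0.227), and adjusted over the list alone Cyp1b1 and Nqo1 passed. Values that did not pass were Hs3st6 at −3.15, Col10a1 at least 10.3-fold higher, Kcnq1 at 3.09 (0.66 on another probe), Mfap3l at −1.39, Xaf1 at 4.24 (0.04 on its other probe), Trp53 at −0.07, Krt5 at 0.13, Krt14 at 0.20, Upk2 at −0.99 and Cdkn1a at −0.55. Without Krt5-Cre replicate 2 the matrix (0.35) and macrophage (0.35) calls were lost, without Upk2-Cre replicate 2 (0.79 and 0.45) and without Trp53 het replicate 1 (0.21 and 0.67) likewise, and the skeletal muscle call without Krt5-Cre replicate 1 (−0.83) or Trp53 het replicate 1 (−1.34). With slide as a block 10 genes were called and with scanner as a block 17, and without Trp53 het replicate 2, 11 lists. Without Upk2-Cre replicate 2 the squamous median was −1.52. The sex label as a covariate ended the matrix (0.21) and macrophage (0.51) calls.

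Contact and structural p53 mutations were compared in 5 R270H and 7 R172H bladders, both drivers weighted alike. Smooth muscle genes were higher with R270H (median 2.21, 14 of 14 above 0, camera adjusted p = 5.79e-17; adjusted p = 0.189 with an estimated correlation), with Synpo2 at 2.98, Synm at 2.86, the actin-binding Tagln at 1.86 and the myosin light chain Myl9 at 2.15. Nerve genes were higher (median 1.63, camera adjusted p = 0.000815; adjusted p = 0.189 with an estimated correlation), with Sox10 of Schwann cells at 1.63. Fibroblast (1.08, with Pi16 at 2.02), endothelial (1.13, with Kdr at 1.21) and NRF2 target and xenobiotic genes (0.74, with Txnrd1 at 0.79 and the xenobiotic gene Cyp1b1 at 2.04) were higher, and these 5 calls held without any 1 array. Epithelial-mesenchymal transition (0.75, with Vim at 1.56), lymphocyte (0.89, with Ms4a1 at least 1.68-fold higher) and adipocyte genes (1.32, with Adig at 1.07) were higher. Male accessory gland genes were called higher too, but their 4 tested members were well above background on at most 1 of the 12 arrays, so they are given no value. Basal (−0.40, with Fat2 at −1.35 and Trp63 at −0.88, or −0.10 on its other probe) and glycolysis genes (−0.32, with Hk2 at −0.97) were lower. All 5 R270H arrays were on slides 1 and 2, and 5 of the 7 R172H arrays on slide 3, read by the other scanner; the 2 Upk2 mutant groups shared no slide. No gene passed in limma over all genes (1 with slide and 17 with scanner as a block; 1712 at an unadjusted p under 0.05, smallest adjusted p = 0.172), and adjusted over the list alone 14 smooth muscle, 5 nerve, 2 fibroblast, 3 NRF2, 1 lymphocyte and 1 basal gene passed. Values that did not pass were Hmgcll1, at least 2.10-fold lower, Wfikkn2 at 2.95, Gpr20 at 2.03, Tppp3 at 1.70, Uchl1 (1.63 ± 0.40, n = 5, against 0.12 ± 0.53, n = 7), Krt5 at −0.43, Krt14 at −0.61, Upk2 at 1.29 and Cdkn1a at 0.49. Trp53 was −0.89 ± 0.47 (SD, n = 5) against −0.28 ± 1.07 (n = 7). The other 9 lists had adjusted p = 0.468 or 0.514 with an estimated correlation.

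The remaining R270H calls rested on few arrays. Without Krt5-Cre R270H replicate 2 the basal (−0.17), epithelial-mesenchymal transition (0.55), glycolysis (−0.06), lymphocyte (0.73), adipocyte (1.20) and male accessory calls were lost, leaving 6 lists called in all, and without Upk2-Cre R270H replicate 2 the lymphocyte call (0.36). The adipocyte and male accessory calls were also lost without Krt5-Cre R270H replicate 1 (adipocyte median 0.88), Krt5-Cre R172H replicate 4 (0.94) or Upk2-Cre R270H replicate 1 (1.19). The adipocyte call was lost without Upk2-Cre R172H replicate 3 (1.32), and the male accessory call without Krt5-Cre R270H replicate 3, Krt5-Cre R172H replicate 3 or Upk2-Cre R172H replicate 1 or 2. Without Krt5-Cre R270H replicate 3, 134 genes passed, 122 higher and 12 lower. The nerve (0.63 and 0.68), lymphocyte (0.29 and 0.34) and adipocyte (0.56 and 0.60) calls were lost with the deposited normalized values and the strict filter, and the former ended the glycolysis call (−0.25). With slide, scanner or replicate number as a block and with array weights the lymphocyte (0.30, 0.31, 0.54 and 0.44) and adipocyte calls (0.63, 0.45, 0.82 and 0.65) were lost as well. The glycolysis call was lost with scanner as a block (−0.48) and array weights (−0.18). Quantile scaling (0.91), no filter and the sex label (1.27) ended the adipocyte call, and no filter the lymphocyte call.

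The animal codes of BBN arrays begin with 1 of 8 parts of unstated meaning. Of 7 Krt5 mutant arrays 1 had the same first part as both Krt5-Cre arrays, and of 5 Upk2 mutant arrays 0 had that of the Upk2-Cre arrays, while all 3 Trp53 het arrays had that of Krt5-Cre. The first part of the code was fitted as a block only after seeing the data. As a fixed block it left only Trp53 het against the Cre controls estimable, so it cannot be told apart from group in the others. There 4 genes were called, the squamous median was −2.16, and the NRF2 (−0.34, camera adjusted p = 0.280) and skeletal muscle (−1.24, camera adjusted p = 0.0629) calls were lost. As a random block it left squamous genes called, at −1.79 for Krt5 mutant against Krt5-Cre and −2.60 for Upk2 mutant against Upk2-Cre. It ended the limma calls of Rwdd3 (adjusted p = 0.118) and of Hddc3 for Upk2 mutant against Upk2-Cre (0.183). Lists whose camera calls it ended were macrophage genes for Krt5 mutant against Krt5-Cre (0.40) and male accessory genes for the driver difference and for R270H against R172H. For Krt5 mutant against Trp53 het these were epithelial-mesenchymal transition (0.27), fibroblast (0.26) and NRF2 genes (0.11). The Krt5 mutant array with the first part of Krt5-Cre had a squamous score of −0.10 and a cell cycle score of 1.77, against means of 2.13 and −0.04 in Krt5-Cre. Its smooth muscle (1.76 against 1.86), nerve (1.47 against 1.29) and macrophage scores (−0.37 against −0.25) lay near the means of Krt5-Cre, while the other 6 Krt5 mutants had means of −0.09, −0.23 and 0.20.

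Under quantile scaling the medians of some lists that were not called changed sign. Besides the p53 targets in BBN bladders these were luminal, male accessory and hedgehog genes for Upk2 mutant against Upk2-Cre and skeletal muscle genes for the driver difference. For Krt5 against Upk2 mutant they were cell cycle, macrophage, male accessory, hedgehog and glycolysis genes. They were neutrophil genes for Krt5 mutant against the other BBN groups, for Krt5 mutant against Trp53 het antigen presentation and glycolysis genes, and for Trp53 het against the Cre controls neutrophil and glycolysis genes. With genes that were well above background in only 1 of 2 groups at their bound, some medians of called lists were nearer 0. For BBN against normal these were squamous (3.69), neutrophil (2.94) and lymphocyte genes (0.88), for Upk2 mutant against Upk2-Cre epithelial-mesenchymal transition (1.26) and endothelial genes (1.80), for Krt5 against Upk2 mutant skeletal muscle genes (1.08), and for Trp53 het against the Cre controls squamous genes (−2.06). The limma and permutation p-values measure spread between samples. Camera at its preset correlation sets a list's genes against all other genes, so its p-values do not measure that spread. Upk2-Cre replicates 1 and 2 share an animal code, but the first had Xist and no Y-linked gene well above background and the second 4 Y-linked genes without Xist, so their RNA came from different mice. Whether Trp53 het replicates 1 and 2, which share another code, were separate mice is not settled. The groups, lists and comparisons were fixed before the data were examined.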

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

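The tests of these differences were set before the data were examined. In 13 gene lists the effect of a Trp53 mutation differed between the Krt5 and the Upk2 driver by a test of the difference itself, in camera at its preset correlation. Relatively higher with the Krt5 driver were cell cycle (median log2 difference 0.91), glycolysis and hypoxia (0.88) and adipocyte genes (1.98). Relatively lower were luminal (−0.32), p53 target (−0.34), epithelial-mesenchymal transition (−1.104), smooth muscle (−1.32), fibroblast (−1.46), endothelial (−1.19), Schwann and nerve (−1.18), male accessory gland (−1.68), NRF2 target (−1.04) and hedgehog pathway genes (−1.13). Each driver has 2 control arrays, and with the correlation between genes estimated from the data 0 of the 13 lists were called. Without Krt5-Cre replicate 1, 3 lists were called, and the fibroblast median was 0.20. Under normexp the hedgehog median was 0.070. The 4 tested male accessory genes were well above background on at most 2 of the 16 arrays, so −1.68 decides nothing.

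Of 13556 tested probes without a gene symbol, left out above, 3141 were higher and 2385 lower in BBN than in normal bladders. What they measure is not given in the sources used here. In the only group of 4 arrays, Krt5-Cre R172H, 27 measures were searched with Dixon's test for an array far from the other 3, and 0 passed. With 4 arrays that test sees only a gap that makes up most of the range, so it leaves less extreme arrays unmarked.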

How the results depend on the processing

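The settings with Xist and Y-linked genes as a covariate, arrays in doubt by sex left out, dim arrays left out, only the scanner of the normal arrays, the first part of the animal code as a block and the fry test were chosen after seeing the data. Of the medians of called lists, 2342 values under other settings kept their direction and side of the threshold, 305 lost the call and 14 reversed; of called genes 2416 kept it, 65 lost it and 1 reversed. Of the 3 called list scores 66 values kept the call and 9 lost it. A fit of only the arrays compared equals the reported one for BBN against normal, which uses all 22. The cause of each change below was not tested unless stated.

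Counts of called genes moved as follows. With normexp 0 passed for Krt5 mutant against Krt5-Cre, 0 for Upk2 mutant against Upk2-Cre and 0 for Krt5 against Upk2 mutant. With quantile normalization these were 5 for Krt5 mutant against Krt5-Cre, 0 for Upk2 mutant against Upk2-Cre and 1 for Trp53 het against the Cre controls. With the deposited table, 0 passed for Upk2 mutant against Upk2-Cre, 0 for Krt5 against Upk2 mutant and 24 for R270H against R172H. With no filter, 1 passed for Krt5 mutant against Krt5-Cre and 0 for Upk2 mutant against Upk2-Cre. With the strict filter, 4602 passed for BBN against normal, 0 for Upk2 mutant against Upk2-Cre and 0 for Krt5 against Upk2 mutant; it tests fewer genes. With the mean over probes 0 passed for Krt5 mutant against Krt5-Cre. With only the arrays compared, and with replicate number as a block, 0 passed for Krt5 mutant against Krt5-Cre, 0 for Upk2 mutant against Upk2-Cre and 0 for Krt5 against Upk2 mutant. With arrays of 1 animal code averaged, 0 passed for Upk2 mutant against Upk2-Cre and 3 for Krt5 against Upk2 mutant. With the sex label as a covariate, 0 passed for Upk2 mutant against Upk2-Cre.

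With slide as a block, 8 genes passed for Upk2 mutant against Upk2-Cre, 0 for Krt5 against Upk2 mutant, 10 for Trp53 het against the Cre controls and 1 for R270H against R172H. With scanner as a block, 5 passed for Krt5 mutant against Krt5-Cre, 2 for Krt5 against Upk2 mutant, 17 for Trp53 het against the Cre controls and 17 for R270H against R172H. Slide could not be fitted as a fixed block for BBN against normal; as a random block 5178 genes passed. With array weights, 13124 passed for BBN against normal, 0 for Krt5 mutant against Krt5-Cre, 2 for Krt5 against Upk2 mutant, 2 for Trp53 het against the Cre controls and 1 for R270H against R172H. With the Xist covariate, 1 passed for Krt5 mutant against Krt5-Cre and 0 for Upk2 mutant against Upk2-Cre. Without the 2 arrays in doubt by sex, 1 gene passed for the driver difference. Without the dim arrays, 0 passed for Krt5 mutant against Krt5-Cre, 2 for Upk2 mutant against Upk2-Cre, 2 for Trp53 het against the Cre controls and 57 for R270H against R172H. With the first part of the animal code as a random block, 1 passed for Krt5 mutant against Krt5-Cre and 0 for Upk2 mutant against Upk2-Cre, and as a fixed block 4 for Trp53 het against the Cre controls, the only comparison it left estimable. On the scanner of the normal arrays alone 8327 passed for BBN against normal.

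Counts of called lists moved too. An estimated correlation left 0 in all 9 comparisons. The fry test called 0 lists in all but BBN against normal (12) and R270H against R172H (2). With the deposited normalized values 5 lists were called for Upk2 mutant against Upk2-Cre, 7 for the driver difference, 2 for Krt5 against Upk2 mutant and 6 for R270H against R172H. With the strict filter these were 5, 8, 3 and 7, and 6 for Krt5 mutant against Trp53 het. Slide as a block and scanner as a block each gave 13 for Krt5 mutant against the other BBN groups. Array weights gave 5 for Krt5 mutant against Trp53 het. Without the 2 arrays in doubt by sex 13 were called for Upk2 mutant against Upk2-Cre.

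These values reversed. With normexp the driver difference had medians of 0.13 in male accessory gland and 0.070 in hedgehog genes. Adipocyte genes of Krt5 against Upk2 mutant had −0.13 with the deposited table and −0.10 with the strict filter, each on 2 of the 8 genes. Xaf1 in Krt5 mutant against Krt5-Cre had −0.78 with the strict filter, because that takes its other probe. The p53 target median of Krt5 mutant against Trp53 het was 0.011 with array weights, and the macrophage median of Krt5 mutant against Krt5-Cre −0.28 without the dim arrays.

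Leaving out 1 array at a time gave from 5057 to 8144 genes for BBN against normal, 0 to 4 for Krt5 mutant against Krt5-Cre, 0 to 1 for Upk2 mutant against Upk2-Cre, 0 to 1 for the driver difference, 0 to 3 for Krt5 against Upk2 mutant, 0 to 1 for Krt5 mutant against the other BBN groups, 0 to 0 for Krt5 mutant against Trp53 het, 0 to 1 for Trp53 het against the Cre controls and 0 to 134 for R270H against R172H. Lists ran in the same order from 11 to 12, 8 to 14, 8 to 13, 3 to 15, 5 to 12, 6 to 12, 5 to 12, 3 to 11 and 6 to 12. Called list scores ran from 0 to 4, with 0 whenever a normal array was left out, since 2 normals allow no smaller adjusted p than 0.0508. Where 1 array was left in a group it was assumed to vary like the other groups. Medians that reversed were, for Krt5 mutant against Krt5-Cre, macrophage (from −0.27 without Krt5-Cre replicate 2 to 1.22), endothelial (from −0.021 without Krt5-Cre replicate 2 to 1.45) and glycolysis genes (from −0.087 without Krt5-Cre replicate 1 to 0.83). For Krt5 mutant against Trp53 het they were matrix (from −0.18 without Trp53 het replicate 2 to 0.78) and fibroblast genes (from −0.056 without Krt5-Cre R270H replicate 2 to 0.79, with −0.00 without Trp53 het replicate 2). The driver difference in fibroblast genes ran from −3.05 to 0.20 without Krt5-Cre replicate 1, and the squamous median of Krt5 mutant against the other BBN groups from −1.24 to 0.074 without Krt5-Cre R172H replicate 3.

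Signal over background limited what was measured. On 3 arrays under 45% of spots were well above background (Krt5-Cre replicate 2 at 44.0%, Krt5-Cre R172H replicates 1 and 2 at 42.4% and 43.0%). Replicate numbers do not pair the arrays: 66 pairs of equal number had a median correlation of 0.027, against −0.006 for 144 others. Arrays of 1 slide had a median correlation of 0.097, against −0.011 otherwise.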

Other observations

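The tests of the sex, muscle wall and Xaf1 explanations, the slide-blocked score and the scores of all 22 lists were chosen only after the result was seen. Some genes followed groups in ways that no comparison asked about. Hddc3 was −2.32 in normal bladders and lower in every BBN group without an activated mutation and in both Krt5 mutant groups (from −4.85 in Upk2-Cre to −4.11 in Krt5-Cre R270H). In the Upk2 mutants it lay at −2.05 with R270H and −1.66 with R172H. The low levels lie near the limit of detection. Hddc3 was well above background on 2 of the 7 Krt5 mutant arrays. On Upk2-Cre replicate 2 the lowest signal well above background was −3.43. Krt5-Cre R172H replicate 3 had the skeletal muscle score 4.35 and the squamous score −3.20.

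Scores were also computed for the lists not scored in the report. BBN and normal bladders differed in neutrophil (4.53), hedgehog (−3.35), cell cycle (3.31), interferon (2.59), NRF2 (−1.43) and glycolysis genes (1.18), each with an exact permutation adjusted p = 0.00159 over all 22 lists. Fibroblast genes differed by −2.05 (exact permutation adjusted p = 0.00714) and lymphocyte genes by 1.26 (0.0182), while smooth muscle genes differed by 1.69 (0.0655) and skeletal muscle genes by 1.69 (0.0923).

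Other splits of the compared arrays were fitted in the same way. For BBN against normal, 1 of 100 splits, the real one, called as many genes (7640 in a fit of 2 sides, 2158 at most elsewhere), so that chance is excluded. For Krt5 against Upk2 mutant 9 of 100 did (real 1, highest 73), so that chance is not excluded. Comparisons with only 2 arrays on a side, and the driver difference, were not split. In 4 further comparisons the real split called 0 genes, so every split called as many and the count decides nothing. These were Krt5 mutant against the other BBN groups (100 of 100, highest 131), Krt5 mutant against Trp53 het (100 of 100, highest 858), Trp53 het against the Cre controls (35 of 35, highest 579) and R270H against R172H (100 of 100, highest 66). The splits with many genes did not all follow slide. The one with 579 sets slide 1 against slide 3, and the smaller sides of those with 858 and 73 hold only arrays of slides 1 and 2. In those with 131 and 66 a side mixed arrays of slides 2 and 3, and with 131 also of slide 1. Whether slide shapes these counts was not tested. With slide as a block Trp53 het against the Cre controls gave 10 genes and R270H against R172H gave 1, and with scanner as a block both gave 17.

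On 11 arrays Xist and the Y-linked genes went against the sex label, 3 of them normal and 8 BBN. Mixed RNA of both sexes cannot be decided: 0 of the 11 had both signals, but Xist with at least 2 Y-linked genes was not counted. Normal arrays exchanged with BBN arrays are excluded, since 3 of 3 normals lay below every BBN array in Krt6a (at most −4.08 against at least 5.69) and above every BBN array in Upk3a (at least 7.41 against at most 2.37). Arrays exchanged within a group cannot give the totals of the normals (3 labelled female, 0 Xist-positive), Upk2-Cre (2 and 1) or Trp53 het (0 and 1), and so are not the only cause for 5 of the 11. For the other 6, in 2 of the 4 discordant BBN groups, the totals are equal, and such an exchange stays open. So does exchange between BBN groups, which would misplace genotypes: of 19 arrays 7 were labelled female and 7 Xist-positive. A wrong sex entry stays open for all 11. No biological explanation was tested.

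Smooth muscle genes were higher in R270H than in R172H bladders, with scores of 1.27 ± 1.14 (SD, n = 5) and −0.79 ± 0.77 (n = 7). The exact permutation p = 0.00631 is not adjusted for picking this list. A single array as the cause is argued against, since the lowest median without 1 array was 1.76. Slide as the whole cause is argued against by the slide-blocked score (2.60, 95% interval 1.16 to 4.04), while slide 2 alone, which holds both alleles, gave 1.47 with a standard error of 1.26 and decides nothing. More of the muscle wall in the R270H pieces stays open, and the nerve list, which it needs to be higher, had a median of 1.63. An effect of the allele, which the design names, stays open too and was not tested apart from it.

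The tested Xaf1 probe was at or above 0.15 on 17 arrays and at or below −4.00 on the 5 Krt5-Cre and normal arrays. An interferon response is argued against by the interferon median of −0.39 in Krt5 mutant against Krt5-Cre bladders. Both Upk2-Cre arrays, without a mutated Trp53 allele, had the probe well above background, so DNA linked to that allele is not the only cause. Linked DNA stays open elsewhere: every group with a mutated allele had the probe on, and 95 tested genes lie between Trp53 and Xaf1. A DNA or transcript variant at 1 probe stays open: the other probe differed by −0.78, with levels between −0.69 and 2.08. No further biological explanation was tested.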
